A study of Anolis sagrei with 2 samples.

How the data were processed

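Lungs of brown anole embryos (Anolis sagrei, a lizard) were taken whole at embryonic day 5 (E5) and embryonic day 6 (E6), loosened with the enzyme dispase and run as single cells on the 10x Genomics Chromium droplet system, per the labels' protocols. Each stage has 1 library. How many embryos went into each is not given in the sources used here. The authors deposited UMI counts (unique molecular identifiers, each tagging 1 captured RNA molecule) per gene and barcode, as whole numbers with no filter on barcodes, per the file headers and the values themselves. Cell Ranger 3.0 and Seurat 3 are named, without role or order, per the submitters' processing notes. The genome build and annotation are not given in the sources used here.

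Both libraries list the same 22962 gene IDs, and 0 rows name no gene. The deposited files do not pair these IDs with gene names, and 0 of them matched the RefSeq gene table of assembly GCF_037176765.1. Marker lists and gene lists fixed before the data were examined could therefore not be used. No cluster was named, no mitochondrial filter was applied, no erythroid cells were set aside, and the planned smooth muscle share, gene list, contractile score and cell cycle results were not run.

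The planned cell call kept barcodes with at least 1/10 of the 99th percentile of the 3000 barcodes with most UMIs. This put the minimum at 2953 UMIs at E5 and at 9544 UMIs at E6, where it left 829 barcodes and passed above most barcodes of the cell mode. From the barcode totals, before any clustering or comparison of stages, a minimum of 1000 UMIs, listed beforehand as another setting, was therefore taken for the reported values, with at least 300 genes. This departs from the design as first written, and for the single-library percentage, the cluster shares and the gene counts over all cells and in all comparable clusters the values under the first rule are given beside the main results. Scrublet, run within each library at an expected rate of 6%, called 2 barcodes at E5 (0.0665%) and 0 at E6. With so few calls the caller was taken not to have worked, which was not tested on known doublets. The 2 barcodes were removed, and the cells are not taken to be free of doublets.

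Cells were clustered with scanpy 1.11.5 on log counts per 10000, with 2000 variable genes chosen within libraries, 30 principal components, 15 exact nearest neighbours and Leiden resolution 0.6 (igraph 0.11.9), without integration. Components were rounded so that every neighbour distance is exact, since rounding-level differences between processors were enough to change the clusters. For the same reason the clustering was repeated from 10 other random starts, and 10 times with each component moved by at most 1 in its last kept decimal, and the tests of single-library clusters and of the lower median CPM within clusters, except the thinning of all cells to 1000 UMIs, were judged over the random starts. In all, 14 settings of the clustering are reported. Exploratory partitions made before the components were rounded are not. A cluster was called comparable with at least 50 cells in each library. Shares of cells carry exact binomial (Clopper-Pearson) 95% intervals. Cluster shares are compared between stages only for clusters found again, with a Jaccard index of at least 0.8, after leaving out the 4671 genes at least 2-fold different between the libraries over all cells or in any comparable cluster. That rule was chosen after seeing the data.

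For E6 against E5, UMIs were summed per library over all cells or within a cluster and divided by the total to give CPM, counts scaled to the same total in each library. The log2 ratio used 0.5 added to each count. A gene with at least 50 UMIs over both libraries was counted as different at an absolute log2 ratio of 1 or more. Ratios carry a conditional exact 95% interval and CPM an exact Poisson interval. Intervals and limits cover counting error only. With 1 library per stage there is no replicate, so no test was run and no difference has a replicate check. A gene at 0 is given a limit of 3 counts over the library. TMM factors (edgeR 4.0.16 in R 4.3.3) and median-of-ratios factors were the other scalings.

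Genes named in the text were to be the largest rises and falls with a symbol. Without symbols, the 2 IDs with the largest rise and the 2 with the largest fall over all cells are given, each with at least 100 UMIs in the higher library and a counting interval that excludes 1.

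Free RNA was estimated from barcodes with 10 to 99 UMIs, taken as empty droplets, using the 10 leading genes of cluster 15. The estimate was 19.8% of UMIs in E5 cells and 1.85% in E6 cells. It counts any true expression of those genes in other cells as free RNA. This weighs more at E5, where those genes were 0.0703% of UMIs in empty droplets, against 1.22% at E6. Cluster 15 held 8 E5 and 86 E6 cells, so the E5 estimate is the less certain one. For a further clustering, UMIs were dropped at random within the clusters of each library alone until each had lost this share of the empty droplet profile.

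The rule for counting genes as different was tested on simulated counts with 200 genes changed. Both libraries were drawn from the same profile with counting error only. The draws hold no variation between embryos or library preparations and no shift of most genes, and the cell call, clustering and scaling were not tested. Over all cells (11218 genes), 100% of the genes changed 4-fold and 94.6% of those changed 2.5-fold were recovered, and 18 of 10989 unchanged genes were called. In cluster 12 (4158 genes) these were 100% and 83.5%, with 30 of 3865 unchanged genes called. Calls of unchanged genes were most frequent in cluster 11, with 90 of 5786 (1.56%). Alternatives covered the cell call, doublets, resolution, separate clustering, scaling, the count minimum, thinning and free RNA.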

Results

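Single-cell RNA profiles of whole anole lungs were compared between embryonic day 5 and embryonic day 6, stages over which, per the series' design text, mesenchyme is on its way to smooth muscle. The E5 library held 21855650 UMIs and the E6 library 42894024. After the cell call, 3004 E5 cells with a median of 4066 UMIs and 1740 genes were kept, and 5741 E6 cells with a median of 3388 UMIs and 1347 genes. Cells took 72.4% of all UMIs at E5 and 89.9% at E6. The rule written before the data were examined would have kept 829 cells at E6. Gene IDs carry no names in these files, so cell populations are given by number.

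**Figure D1:**
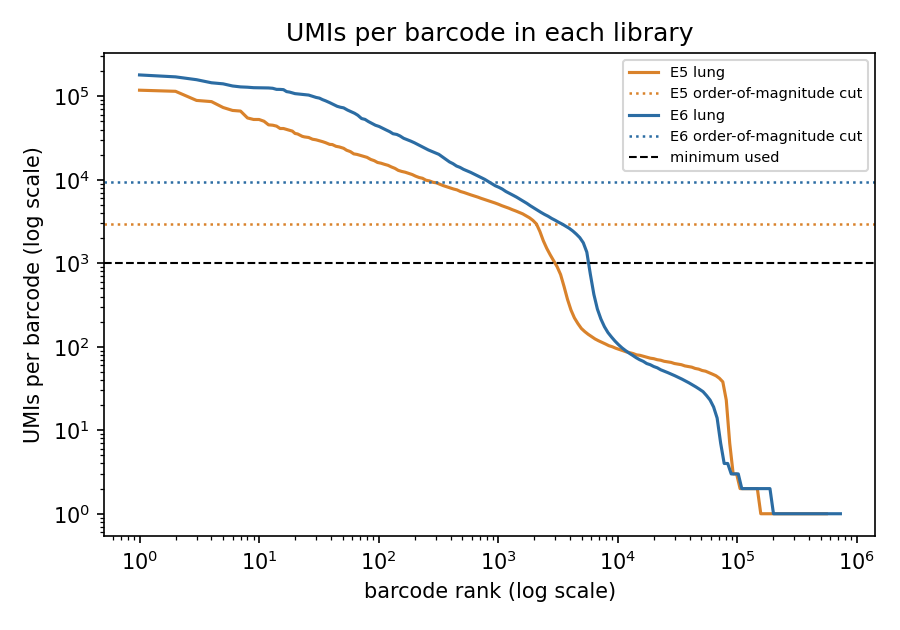
UMIs per barcode against barcode rank (both log scales) for the E5 and E6 libraries, with the minimum used (1000 UMIs, dashed) and the order-of-magnitude cut of each library (dotted). The dotted line lies at 2953 UMIs for E5 and at 9544 for E6.

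Clustered together, most cells of the lung fell into clusters drawn almost entirely from 1 library. The 8745 cells formed 15 clusters, and 8 of these took at least 90% of their cells from 1 library, 2 from E5 and 6 from E6. They held 76.8% of all cells (95% interval 75.9% to 77.7%), from 69.7% to 78.4% in 10 other random starts of the clustering, and from 65.3% to 84.8% in 10 repeats with the components moved in their last kept decimal. Under the cell call as first written the percentage was 85.4%. Cluster 1 had 11 E5 and 2091 E6 cells, and cluster 2 had 969 E5 and 23 E6 cells. A cluster mostly of 1 library can be that library and not a cell type. With each gene centred within its library, an alternative chosen after seeing the data, the percentage was 38.8%, and in 10 other random starts from 12.04% to 36.6% with a median of 22.4%. Other alternatives chosen then gave 59.1% without the genes that differ between the libraries, and 6.77% or 32.5%, by choice of variable genes, with all cells thinned to 1000 UMIs, where other clusters merged too.

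**Figure D2:**
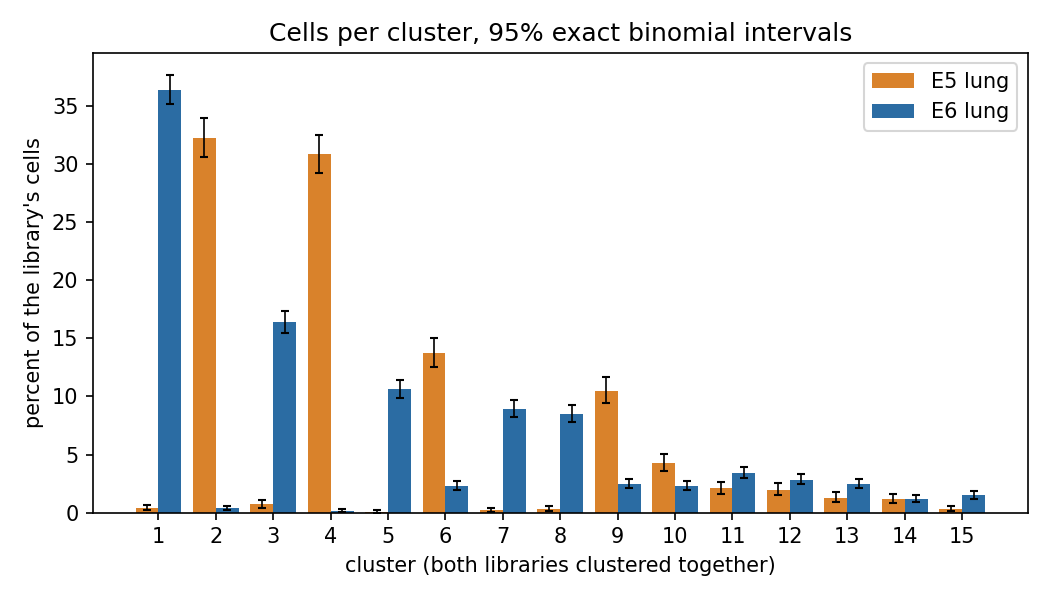
Percent of each library's cells (vertical axis) in each of the 15 clusters, with exact binomial 95% intervals as error bars. Cluster 1 holds 36.4% of E6 cells and 0.366% of E5 cells, and cluster 2 holds 32.3% of E5 cells and 0.401% of E6 cells.

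Populations of the separate stages nevertheless paired by their profiles. E5 cells alone formed 11 clusters and E6 cells alone 14, and 11 pairs were each other's best match. Pearson r of the paired profiles ran from 0.52 to 0.88 across 2000 variable genes, which are not independent replicates. The pairs held 100% of E5 and 78.8% of E6 cells. In 2 pairs the next best match came within 0.1 of the best. In 5 of the 11 pairs both members lay mostly in the same cluster when the libraries were clustered together. The largest E5 cluster (28.7% of E5 cells), mostly in cluster 4, paired with the largest E6 cluster (25.3% of E6 cells), mostly in cluster 1, with r = 0.76 and a next best of 0.62.

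**Figure D3:**
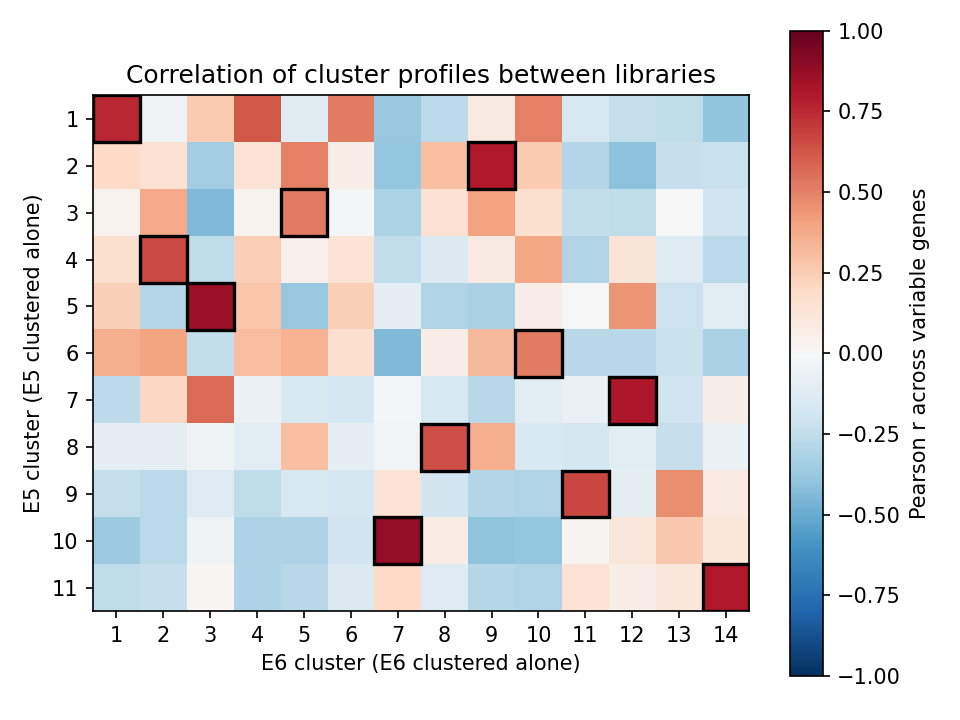
Pearson r across 2000 variable genes between the profiles of clusters found in E5 alone (vertical axis) and in E6 alone (horizontal axis), each profile relative to its own library's mean. Black boxes mark the 11 reciprocal best matches, with r from 0.52 to 0.88.

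Clusters 11, 12, 13 and 15 were the populations found again without the genes that differ between the libraries, and the lowest Jaccard index over the 10 other random starts was 0.921, for cluster 12. Cluster 11 made up 2.10% of E5 cells (1.62% to 2.68%) and 3.41% of E6 cells (2.96% to 3.92%), or 1.83% and 3.45% in the clustering without those genes. Its E5 share was lower with each library clustered alone (1.198%, against 3.45% at E6) and with a minimum of 2000 UMIs (1.37%, against 2.76%). Cluster 12 made up 1.96% (1.498% to 2.53%) and 2.84% (2.42% to 3.30%), or 1.56% and 2.86%, and 2.597% and 2.93% with each gene centred within its library. Cluster 13 made up 1.30% (0.925% to 1.77%) and 2.49% (2.10% to 2.93%), or 1.33% and 2.37%. Cluster 15 held 8 E5 and 86 E6 cells, a share 5.62 times as high at E6 (counting interval 2.73 to 13.4), with 0.233% and 1.41% in the clustering without those genes, and in it 10 genes took 65.4% of UMIs. Cluster 14, below the limit with a Jaccard index of 0.779, held 35 E5 and 69 E6 cells. With each library clustered alone, the E6 cluster that lay in cluster 13 (2.51% of E6 cells) paired with an E5 cluster of 2.36% of E5 cells. Only 54.9% of that E5 cluster lay in cluster 13 (Jaccard index 0.549). The separate clustering therefore does not give the E5 share of cluster 13, and its difference was seen only with the libraries clustered together. For cluster 12, the E6 cluster that lay in it (2.89% of E6 cells) paired with an E5 cluster of 4.56% of E5 cells. Of that E5 cluster 48.2% lay in cluster 6, and it overlapped the E5 cells of cluster 12 with a Jaccard index of 0.371. This pair leaned the other way, but it does not give the E5 share of cluster 12. No E5 cluster lay mostly in cluster 12 or 15. Under the cell call as first written, clusters 11, 12 and 13 held 1.58%, 2.49% and 1.196% of E5 cells and 8.81%, 5.31% and 9.05% of E6 cells. Cluster 15 was not found under that call (highest Jaccard index 0.0755). Dissociation, the UMI minimum and depth can set these shares, and in cluster 11 the median was 2042 UMIs at E5 and 4984 at E6.

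Over all cells, more genes were lower than higher at E6 by CPM. Of 11218 genes, 395 were at least 2-fold higher and 2170 at least 2-fold lower, and 352 and 2559 under the cell call as first written. The median gene moved by a log2 ratio of -0.49, so these counts depend on the scaling. In 10 equal groups of genes by mean CPM, the median log2 ratio was -0.49 in the lowest group, -0.68 in the next and -0.23 in the highest, so no single scaling centres genes of every level. Under median-of-ratios scaling, a shift of -0.55, 986 genes were higher and 757 lower, and under TMM, a shift of -0.53, 967 and 773. The share of higher genes among those counted was 15.4% by CPM, 56.6% by median of ratios and 55.6% by TMM.

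ASU_Acar_G.22894 had 0 UMIs in E5 cells, which allows up to 0.190 CPM, and 3617 in E6 cells, or 93.8 CPM (90.8 to 96.9), at least 495-fold higher. It had UMIs in all 13 clusters with at least 50 E6 cells, from 50.4 to 146 CPM. ASU_Acar_G.18204 had 0 UMIs in E5 cells and 633 in E6 cells, or 16.4 CPM (15.2 to 17.8), at least 86.6-fold higher, also in all 13. ASU_Acar_G.6972 had 214 UMIs in E5 cells, or 13.5 CPM (11.8 to 15.5), and 0 in E6 cells, which allows up to 0.0778 CPM, at least 174-fold lower. Cluster 2, which had 23 E6 cells, held 91.6% of its E5 UMIs. ASU_Acar_G.17260 had 169 UMIs in E5 cells and 1 in E6 cells, a 412-fold fall with a counting interval of 72.9 to 16362. The counts of 0 hold for cells only: empty droplets held 3 UMIs of ASU_Acar_G.22894 and 2 of ASU_Acar_G.18204 at E5, and 4 of ASU_Acar_G.6972 at E6. These 4 differences have no replicate check and can belong to the embryos sampled.

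Within clusters the same lean was seen. Clusters 6, 9, 10, 11 and 12 had at least 50 cells in each library, of which 9 and 10 formed differently in other random starts (lowest Jaccard index 0.259 and 0.44). Clusters 6, 9 and 10 were not found again without the genes that differ between the libraries (Jaccard index 0.276, 0.216 and 0.155). With each library clustered alone, the E5 and E6 clusters mostly in cluster 6 did pair (r = 0.80), though only 56.5% of that E6 cluster lay in it. Those mostly in cluster 10 also paired (r = 0.81). The E5 cluster mostly in cluster 9 paired with an E6 cluster of which 78.8% lay in cluster 5 (r = 0.86), so cluster 9 holds at most a part of that E6 population. By CPM, 111, 149, 107, 198 and 167 genes were at least 2-fold higher in clusters 6, 9, 10, 11 and 12, in that order, and 1005, 810, 512, 1099 and 588 lower, with median log2 ratios of -0.44, -0.28, -0.30, -0.48 and -0.34. Under median-of-ratios scaling 323, 268, 257, 648 and 502 were higher and 411, 530, 223, 222 and 167 lower. Clusters 10, 11 and 12 thus turned to more higher than lower genes. Those clusters also had more UMIs at E6 than at E5, as did all cells together, and clusters 6 and 9 had fewer. A minimum on UMIs summed over both libraries favours genes high in the library with more UMIs. It can therefore make part of this turn, which was not tested. Of 3772 genes measured in all 5 clusters, 12 were higher and 31 lower in every one. Independent clusters would give 1.07e-05 and 0.0348, but clusters of the same 2 libraries are not independent. Under median of ratios the genes higher and lower in every cluster were 39 and 7, and under the cell call as first written 11 and 35. In the other random starts, with 4 to 6 comparable clusters, they ran from 12 to 18 and from 31 to 70 by CPM. Log2 ratios of the clusters correlated across genes with r of 0.42 to 0.69 over 10 pairs. All clusters share the same 2 libraries, so part of this can be the library.

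**Figure D4:**
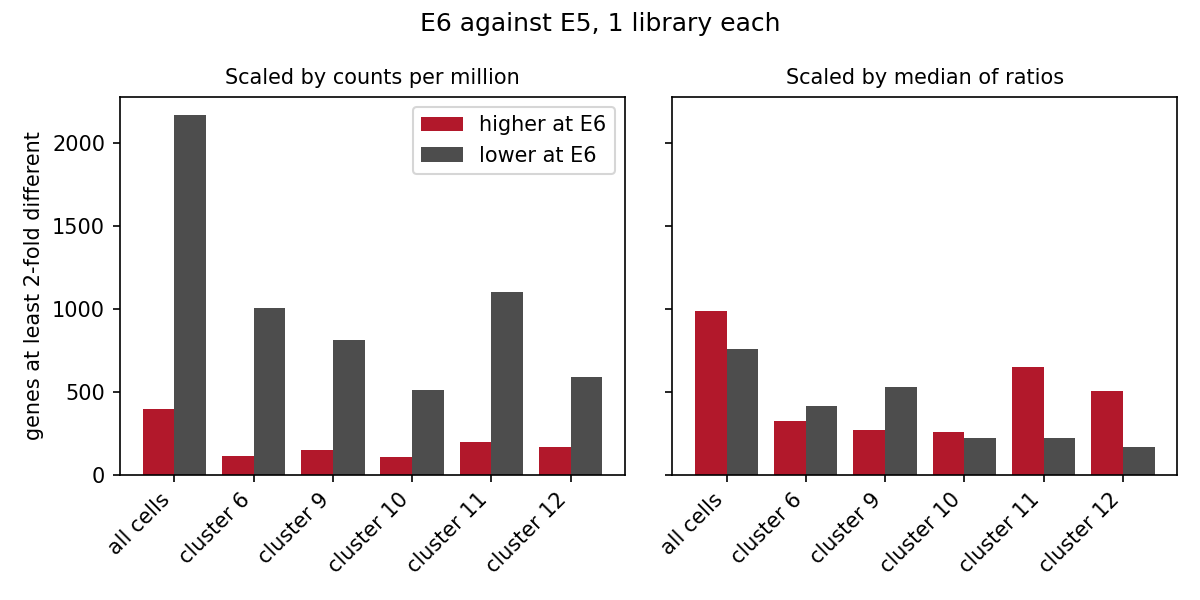
Genes at least 2-fold higher or lower at E6 than at E5 (vertical axis, number of genes) over all cells and in the 5 comparable clusters, scaled by CPM (left) and by median of ratios (right), 1 library per stage. Over all cells 395 genes are higher and 2170 lower by CPM, and 986 and 757 by median of ratios.

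E6 cells also spread their UMIs over fewer genes. With every cell thinned to 1000 UMIs, the median was 636 genes at E5 and 553 at E6, against 1740 and 1347 unthinned, and 0 kept cells were too shallow to thin. It was lower at E6 in all 5 comparable clusters, for example 623 against 539 in cluster 6 and 641 against 543 in cluster 12. Genes per cell were not recounted with free RNA removed, estimated at 19.8% of UMIs in E5 cells and 1.85% in E6 cells. Its part in this difference was therefore not tested. The 100 genes with most UMIs in each library took 38.1% of UMIs at E5 and 49.4% at E6.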

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

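Among genes measured in all 5 comparable clusters, 32 were at least 2-fold higher at E6 in one cluster and at least 2-fold lower in another, with both counting intervals excluding 1. The difference between clusters was not tested, since each stage has 1 library. Clusters 6, 9 and 10 were not found again without the genes that differ between the libraries. Within them the E5 and E6 cells may be unlike, and the part of this in the opposite calls was not tested. No range over other random starts is given for this number. In 20 simulated draws with no gene changed, at most 2 genes did so, but the draws hold counting error only and not the variation between embryos or library preparations. Under median-of-ratios scaling the number was 44, and 17 genes were in both sets.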

How the results depend on the processing

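No paired analysis was possible because each stage has 1 library and no test was run. Alternatives that need gene names (for the smooth muscle share, gene lists, contractile score and cell cycle) were not run. Doublet scores, centring, removing free RNA before clustering, moved components, thinning to 1000 or 3000 UMIs, other random starts and leaving out differing genes or clusters were chosen after seeing the data. Of 178 values of the main results under alternatives, 127 kept to the limits set for them, 49 moved and 2 reversed. Each value was judged alone, so a turn in the balance of higher and lower genes is counted as moved. Of 110 counts within single clusters, 72 stayed within 1.5 times and 38 did not. Where no cause is given, the cause was not tested.

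The cell call as first written kept 829 E6 cells, with 85.4% of cells in single-library clusters. Clusters 11, 12 and 13 then held 8.81%, 5.31% and 9.05% of E6 cells, cluster 11 held 1.58% of E5 cells, and cluster 15 was not found. Lower calls in clusters 6, 9, 10, 11 and 12 were then 1237, 1186, 578, 1093 and 536, and higher calls 99, 176, 106, 200 and 140. A minimum of 2000 UMIs gave 1.37% and 2.76% of E5 and E6 cells in cluster 11. Resolution 1.2 gave 24 clusters and 79.0% in single-library clusters. Keeping the 2 called doublets gave 71.6%, other random starts 69.7% to 78.4%, and moved components 65.3% to 84.8%, so this percentage moves beyond its counting interval with the partition alone. Removing the highest doublet scores gave 71.6%, leaving out differing genes 59.1%, and centring 38.8% (12.04% to 36.6% in 10 other starts), with 2.597% of E5 cells in cluster 12. Removing free RNA gave 81.2% (68.7% to 88.0% in 10 other starts). Thinning to 1000 UMIs gave 7 clusters and 6.77%, or 8 clusters and 32.5% with the variable genes of unthinned cells. Cells of 3000 or more UMIs gave 85.4% unthinned and 63.9% thinned (76.0% to 85.1% and 62.1% to 81.2% in other starts). Clustered alone, E5 had 1.198% of cells in the cluster matching cluster 11. The E5 cluster nearest cluster 13 held 2.36%, but only 54.9% of it lay in cluster 13. No E5 cluster lay mostly in 12 or 15. The pair nearest cluster 12 held 4.56% of E5 and 2.89% of E6 cells. Of its E5 cells 48.2% lay in cluster 6, so these are not shares of cluster 12.

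Scaling moved the gene counts by its construction. TMM gave 967 higher and 773 lower genes over all cells with a median log2 ratio of 0.0417, and median of ratios 986, 757 and 0.0540, each reversed from -0.49. Summed over clusters, 732 higher and 4014 lower calls became 1982 and 1570 by TMM and 1998 and 1553 by median of ratios. Genes higher and lower in all clusters became 34 and 7, and 39 and 7. A minimum of 200 UMIs tests fewer genes and gave 219 and 1297 over all cells, 244 and 883 summed, and 2 lower in all clusters. With no minimum but a UMI required in each library, which drops genes at 0 in either, these were 628 and 4192, 3119 and 12771, and 162 lower in all clusters. Other random starts gave up to 70 lower in all clusters. Of the 395 higher and 2170 lower genes, 258 and 1787 remained under the cell call as first written, where 3 of the higher genes turned to at least 2-fold lower, 395 and 757 under median of ratios, and 385 and 2169 with no minimum.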

Other observations

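All tests here were chosen after the result was seen except 2, the tests of depth and of abundant genes over all cells for the lower median CPM.

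ASU_Acar_G.22894 had no UMI in E5 cells and UMIs in every comparable cluster at E6, with 3 UMIs in E5 empty droplets against 230 at E6. Free RNA is argued against, since its CPM in E6 cells was 96.8% of that in empty droplets, against an estimated free RNA share of 1.85%. Lower depth at E5 is also argued against, since 1484 UMIs would be expected there at the E6 rate. E6 cells without a UMI were 1.02 times the Poisson number, but genes of like total ran from 0.970 to 1.07 and 25% of cells from embryos without the gene would give 1.05, so this test decides nothing. A difference between embryos (sex, genotype or a variant against the reference) and one between stages cannot be told apart with 1 library each, 2 genes with at least 100 UMIs show this pattern, and the source of the 3 UMIs at E5 was not tested.

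Most cells lay in single-library clusters. Among cells of 3000 or more UMIs, unequal depth per cell is argued against as the whole cause, since 63.9% did so when thinned to 3000 UMIs (62.1% to 81.2% in 10 other random starts), against 85.4% unthinned (76.0% to 85.1%). With shallower cells included depth stays open: thinning to 1000 UMIs, tried first, gave 6.77%, or 32.5% with the variable genes of unthinned cells, both below 0.5 times the main value, but clusters 11 and 13 dissolved in both (Jaccard index 0.468 and 0.273, or 0.453 and 0.271) and cluster 12 in the first (0.101, against 0.664). Free RNA at the estimated shares is argued against as the whole cause, since with it removed from each cell 81.2% did so (68.7% to 88.0% in the other starts). A shift of each gene by the same amount in all cells of a library, from stage or from library preparation, may account for much of it and stays open, since centring left 38.8%, just above the limit of 0.5 times the main value, and 12.04% to 36.6% (median 22.4%) in the other starts, all below it.

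The median gene had a lower CPM at E6. Cells thinned to 1000 UMIs had fewer genes at E6 in 5 of 5 clusters, which argues against unequal depth for genes per cell. That test does not measure CPM. With UMIs thinned to equal medians the median log2 ratio over all cells was -0.49. Random thinning keeps each gene's expected share of UMIs, so it could hardly move this ratio. For the median CPM, unequal depth therefore stays open. The median was also lower inside every comparable cluster (highest log2 ratio -0.28, at most -0.28 in the other starts). In those clusters a change in cluster shares is therefore not needed for it. Most cells could not be checked in this way, since 76.8% lay in single-library clusters, so another mix of populations stays open over all cells. Without the 100 genes with most UMIs the median over all cells went from -0.49 to -0.20, and those of clusters 6, 9, 10, 11 and 12 to -0.12, -0.11, -0.094, -0.069 and 0.011. A few abundant genes may therefore account for part of the shift over all cells and for most of it within clusters. This stays open, since a single shift for all other genes would not differ by level as found over all cells (-0.68 in group 2 of 10 by mean CPM, -0.23 in the highest). In the main clustering 3 of 5 clusters passed the limit of -0.1. In most other starts those passing were no majority (from 2 to 3, with 4 to 6 comparable clusters). Stage and library cannot be told apart here.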
